A study of Mus musculus with 6 samples.

How the data were processed

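Poly(A) RNA of a mouse FRC line was sequenced on an Illumina NextSeq500 from directional libraries made with 500 ng of total RNA, per the labels' protocols. Cells had been kept for 96 h, with a change of medium every 48 h, in medium that FRCs, 67NR cells or 4T1 cells had conditioned for 24 h and that was supplemented with 2% serum. The authors deposited raw read counts per gene symbol, as whole numbers, in an unfiltered and a filtered table. Per the submitters' processing notes, reads were counted with Subread on mm10 and analysed with DESeq2 1.32.0. The aligner settings and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes are uncertain, as are near-identical paralogs (Saa, Serpina3, Ly6, Oas, H2 and Wfdc families). The filtered table held the same values for 14629 genes. The unfiltered table was used here, with 55367 symbols, of which 53365 matched GENCODE M21 (GRCm38, the same assembly as mm10), as did 14747 of the 15055 tested. Gene positions come from that annotation.

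Groups followed the media, with 2 libraries each and 6 in all. Total counts per library ranged from 13.6 M to 21.8 M (M, 1e6 counts), so that a single count stood for 0.0463 to 0.0743 CPM. Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 15055, and scaled by the trimmed mean of M-values (TMM). CPM values use the library totals of the tested genes multiplied by that scaling factor. A quasi-likelihood fit of all 6 libraries, with 3 residual and 9.62 prior degrees of freedom, a common biological coefficient of variation of 5.81% and a prior count of 0.125, gave log2 fold changes and F tests for the 3 comparisons, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Fits used R 4.3.3, and figures used Python 3.11.15 with matplotlib 3.10.9. Where a group had no counts, the fold was computed against 3 counts over the group, and with 1 to 3 counts a ratio with a 95% counting interval is given, both at TMM-scaled library totals.

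The tests, the alternatives, 32 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover stroma markers, chemokines, TLR4 and NF-kB signalling, interferon, matrix, growth, metabolism, stress, other cell types and RNA quality. Those with at least 5 tested genes, 30 in number, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, in both directions, and again with an estimated correlation and with fry. Counts of list members are given over all genes tested. They were the same adjusted over the list alone unless another count is printed. Some genes stand in more than 1 list, such as Saa3, Lcn2 and C3. The list called p53 targets for short also holds cell cycle arrest genes such as Cdkn1b. With an estimated correlation the calls that held were complement and acute phase and NF-kB targets in both comparisons of 4T1 medium, and no list held for 67NR against control. The naming rule took, per comparison, the 6 largest rises and 6 largest falls among genes past the threshold with at least 10 CPM in the higher group and no overlap between groups, up to 3 members of each called list, 1 of each other list, and 10 genes regardless of value (Tlr4, Ccl2, Ccl7, Cxcl1, Il6, Pdpn, Ccl19, Ccl21a, Acta2 and Fap). It gave 77, 72 and 75 entries, more than the limit of 30, and the text names part of them. The planned order, largest adjusted p left out first, was not kept for the examples of a list, so the choice among qualifying genes was made after their values were seen. Genes outside the rule in the plot of expression levels, such as Bcl3, Mki67 and Top2a, and those in the other observations were chosen after their values were seen.

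The alternatives were DESeq2 size factors, library totals alone, no filter, the genes of the filtered table, 10 counts in every library of a group, the replicate number as a block, each library left out in turn, fits of the 2 groups compared (4 libraries), limma-voom, the Wald test of DESeq2 1.42.0 and a 2-fold minimum. Ranges of camera adjusted p over the alternatives leave out the estimated correlation and fry, which are given apart. Thinning of all libraries to the smallest total was added after the data had been seen. Both tumour media share the control libraries, so their covariance was set against 20 simulations without effect.

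The code was tested on simulated counts drawn, for all groups, from the means of the control libraries at the real library sizes, with 200 genes changed. For 4T1 against control, run on 14565 genes, 43.3% of changes of 0.5 on the log2 scale were recovered, 91.3% of changes of 1 and 92.2% of changes of 2, and 4.43% of calls were false. For 67NR against control (14570 genes) the shares recovered were 58.8, 84.7 and 92.2%, with 10.5% of calls false, and for 4T1 against 67NR (14564 genes) 56, 88.9 and 96.8%, with 7.6% false. In each of the 3 comparisons the list that had been shifted was called, and 0 of the others. Genes were drawn independently of each other, so the simulation does not show how often correlated genes give false list calls. In the comparisons with 67NR medium the share of false calls was above the threshold of 0.05. In the data 27.6 to 43.4% of genes were called, far more than were changed here, so these shares may not carry over.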

Results

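Messenger RNA was sequenced from a mouse line of fibroblastic reticular cells (FRCs), the stromal cells that build the conduit scaffold of lymph nodes, after 96 h in conditioned medium. The 6 libraries formed 3 groups of 2. Control medium came from FRCs themselves, and the tumour media came from 67NR and 4T1, mouse mammary carcinoma lines of common origin, of which 67NR is known as non-metastatic and 4T1 as metastatic. Total counts per library were 19.3 M and 13.6 M in control medium, 21.8 M and 20.9 M in 67NR medium, and 14.5 M and 18.2 M in 4T1 medium (M, 1e6 counts). A single count stood for 0.0463 to 0.0743 counts per 1e6 (CPM), depending on the library. Of 55367 gene symbols, 26346 had a count and 15055 were tested. Libraries of the same medium correlated at 0.992 or more across genes (Pearson, log CPM), and libraries of different media at 0.979 or less. The first principal component, 63.8% of the variance, set both 4T1 libraries apart from the other 4, and the second, 23.8%, set 67NR apart from control. Variation between libraries of the same medium exceeded counting noise by a factor of 3.97 in control, 3.99 in 67NR and 7.61 in 4T1 medium. The labels do not say whether the libraries of a group are separate cultures, so they may be technical replicates, and the p-values measure only the spread between these samples. Intervals and floors cover counting error only. Mitochondrially encoded transcripts took 1.3 and 1.87% of counts in control replicates 1 and 2, 1.96 and 2.28% in 67NR and 2.11 and 2.37% in 4T1. Ccl19 and Ccl21a, the homeostatic chemokines of lymph node stroma, had 0 counts in all 6 libraries, and a group count of 0 allows up to 3 counts. Ccl21a has near-identical copies, so its reads may have been left uncounted.

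The comparison of 4T1 medium with control medium asks how FRCs respond to medium of metastatic tumour cells in place of their own. The study concerns TLR4 signalling between lymph node fibroblasts and monocytes. No group had unconditioned medium. For either tumour medium, factors released by tumour cells, missing FRC factors and nutrients used up during conditioning therefore cannot be told apart. Genes of the acute-phase response rose most. Lcn2 (chromosome 2, 32384633 to 32388252), which encodes the siderophore-binding protein lipocalin 2, rose from 1.94 ± 0.118 to 2612 ± 70.3 CPM (mean ± SD, n = 2 per group), a log2 fold change of 10.38 (SE 0.12, edgeR quasi-likelihood adjusted p = 8.19e-15). Saa3, a serum amyloid A, rose from 0.39 ± 0.184 to 869 ± 10.5 CPM (log2 11.18, SE 0.14), and complement C3 (chromosome 17, 57203970 to 57228136) from 3.99 ± 0.872 to 642 ± 69.6 CPM (log2 7.36, SE 0.13). Il6 (chromosome 5, 30013114 to 30019981), the cytokine that drives acute-phase synthesis, rose from 1.87 ± 0.0815 to 75.4 ± 7.99 CPM (log2 5.33, SE 0.14). Genes of cholesterol synthesis, cell division and several matrix proteins were lower. Across all genes tested, 2995 were higher and 2893 lower, 39.1% of 15055, with 815 and 620 of them at least 2-fold, by edgeR quasi-likelihood with Benjamini-Hochberg adjustment.

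Of the 14 tested genes of complement and the acute phase, 12 rose and none fell, with a median log2 fold change of 5.65 (3.66 with the 2 genes at 0 in control medium set to their bound) and camera adjusted p = 1.64e-90, or adjusted p = 0.0388 with an estimated correlation. The Saa and Serpina3 families hold near-identical copies, so the share of reads credited to any member is uncertain. Serpina3n, a protease inhibitor of the acute phase, had 2 counts in control and 7341 in 4T1 medium, a ratio of 3622 at TMM-scaled library totals (95% counting interval 1002 to 29916). Wfdc17, a small secreted inhibitor of the whey acidic protein family, went from 3 counts to 6627, a ratio of 2180 (746 to 10574). Slfn2 and Npy4r had no counts in control medium and were at least 146-fold and 115-fold higher in 4T1 medium, against a floor of 3 counts over the group. Of 21 NF-kB target genes, 17 rose and 1 fell (median log2 1.69, camera adjusted p = 1.87e-55, or adjusted p = 0.0388 with an estimated correlation). Lcn2, Saa3 and C3 stand in this list as well as in the previous list, and Ptgs2, the inducible prostaglandin synthase, rose from 19.5 ± 1.17 to 131 ± 26 CPM. The bound left the NF-kB median at 1.69.

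Among 11 myeloid chemokines and growth factors, 6 rose and 2 fell, or 3 fell adjusted over the list alone (median log2 2.02, camera adjusted p = 5.43e-16, or adjusted p = 0.0876 with an estimated correlation). The monocyte chemoattractants Ccl2 (chromosome 11, 82035571 to 82037453) and Ccl7 (chromosome 11, 82045712 to 82047525) rose from 14 ± 2.17 to 86.5 ± 8.94 CPM (log2 2.65, SE 0.11) and from 26 ± 0.826 to 152 ± 8.65 CPM (log2 2.55, SE 0.08). The neutrophil chemoattractants Cxcl1 and Cxcl5 rose from 80 ± 0.616 to 439 ± 21.2 CPM and from 0.858 ± 0.259 to 55.6 ± 7.62 CPM. Of 18 genes of the TLR4 receptor and its adaptors, 7 rose, 1 fell and 10 did not pass (median log2 0.21, camera adjusted p = 0.000144, or adjusted p = 0.172 with an estimated correlation). Tlr4 itself (chromosome 4, 66827584 to 66930284), the receptor for lipopolysaccharide and several endogenous ligands, rose from 25 ± 1.2 to 41.7 ± 7.01 CPM (log2 0.74, SE 0.11, edgeR quasi-likelihood adjusted p = 0.000217). The lipopolysaccharide-binding protein Lbp rose from 0.991 ± 0.14 to 257 ± 22.9 CPM, the co-receptor Cd14 from 1.36 ± 0.35 to 13.3 ± 0.836 CPM and the adaptor Myd88 from 27.3 ± 0.973 to 55.5 ± 2.63 CPM. Of 12 TLR4 ligands and alarmins, 6 rose and 3 fell (median log2 0.18, camera adjusted p = 1.79e-06, or adjusted p = 0.0986 with an estimated correlation). Saa3 and the proteoglycan decorin (Dcn, log2 1.97) rose, and tenascin C (Tnc, log2 -3.77) fell.

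Of 12 FRC and lymph node stroma markers, 7 rose and 2 fell (median log2 0.51, camera adjusted p = 3.19e-06, or adjusted p = 0.15 with an estimated correlation). The alarmin Il33 rose from 54.3 ± 4.79 to 288 ± 19.3 CPM, the adhesion molecule Vcam1 from 206 ± 7.98 to 627 ± 27.3 CPM and the growth factor receptor Pdgfra from 33.7 ± 1.01 to 128 ± 21.9 CPM. Podoplanin (Pdpn, chromosome 4, 143267431 to 143299564), the glycoprotein that defines FRCs, was 105 ± 6 CPM against 124 ± 7.67 CPM, which passed (log2 -0.24, SE 0.08, edgeR quasi-likelihood adjusted p = 0.0304). Its call ended without control replicate 2 (adjusted p = 0.224, with a range of 0.00783 to 0.224 over the alternatives), without 4T1 replicate 1 (adjusted p = 0.071) or at equal depth (adjusted p = 0.0557). Of 25 interferon response genes, 17 rose and 1 fell (median log2 1.29, camera adjusted p = 4.23e-05, or adjusted p = 0.549 with an estimated correlation). Among them were the GTPase Iigp1, from 0.988 ± 0.075 to 11.5 ± 0.718 CPM, and Oasl2, from 4.06 ± 0.0622 to 15.6 ± 4.67 CPM. Of 11 immune checkpoints and suppressive factors, 6 rose and 1 fell (median log2 0.72, camera adjusted p = 0.00172, or adjusted p = 0.15 with an estimated correlation). The prostaglandin synthases Ptgs1 (log2 2.61) and Ptgs2 (log2 2.76) rose in that list, and the galectin Lgals1 (log2 -1.08) fell.

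Of 20 contractile and myofibroblast genes, 14 fell and none rose (median log2 -0.43, camera adjusted p = 0.00011, or adjusted p = 0.128 with an estimated correlation). Tropomyosin Tpm1 fell from 1887 ± 19 to 915 ± 52.4 CPM, calponin Cnn2 from 715 ± 27 to 364 ± 11.2 CPM and smooth muscle actin Acta2 (chromosome 19, 34241090 to 34255590) from 3539 ± 95.7 to 2652 ± 124 CPM. The fibroblast activation protease Fap stayed near the detection limit, at 0.312 ± 0.133 against 0.445 ± 0.104 CPM (edgeR quasi-likelihood adjusted p = 0.44). Of 20 collagens, 13 fell and 4 rose (median log2 -0.51, camera adjusted p = 4.23e-05, or adjusted p = 0.44 with an estimated correlation). Col12a1, Col11a1 and Col8a1 fell by 2.46, 1.43 and 1.36 on the log2 scale. Matrix glycoproteins as a list did not pass, yet hyaluronan synthase Has2 rose from 17.6 ± 0.656 to 298 ± 30.3 CPM. The largest falls among genes of at least 10 CPM were in Ndnf (log2 -6.06, 30.7 ± 0.369 to 0.454 ± 0.0264 CPM), a secreted neurotrophic factor, Gxylt2 (log2 -4.45), Itgbl1 (log2 -4.42), Prr5l (log2 -4.37), the aldehyde dehydrogenase Aldh1a7 (log2 -4.26) and the chemerin receptor Cmklr1 (log2 -4.11).

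All 23 tested genes of cholesterol biosynthesis and uptake fell (median log2 -0.84, camera adjusted p = 2.83e-16, or adjusted p = 0.15 with an estimated correlation). Isopentenyl diphosphate isomerase Idi1 (chromosome 13, 8885501 to 8892451) fell from 131 ± 17 to 45 ± 3.44 CPM, Hmgcs1 from 407 ± 26.7 to 199 ± 11 CPM and the sterol carrier Stard4 from 93.5 ± 6.77 to 40.2 ± 3.91 CPM. All 25 mitosis genes fell (median log2 -0.86, camera adjusted p = 2.76e-11, or adjusted p = 0.355 with an estimated correlation). Likewise 24 of 27 DNA replication and S phase genes fell, 26 adjusted over the list alone (median log2 -0.65, camera adjusted p = 2.19e-08, or adjusted p = 0.26 with an estimated correlation). Examples were the anaphase activator Cdc20, the kinase Plk1 and the helicase subunit Mcm5, which fell by 0.76, 1.02 and 1.00 on the log2 scale. Of 24 amino acid stress and ATF4 target genes, 18 rose and none fell (median log2 0.49, camera adjusted p = 6.18e-09, or adjusted p = 0.172 with an estimated correlation). They were led by cystathionine lyase Cth (17.3 ± 0.918 to 87.7 ± 1.33 CPM), with Trib3 (log2 1.27) and Atf3 (log2 1.70). The unfolded protein response list of the endoplasmic reticulum went the other way, with 15 of 19 genes lower (median log2 -0.48, camera adjusted p = 4.24e-06, or adjusted p = 0.15 with an estimated correlation). Calreticulin (Calr) fell from 2300 ± 7.79 to 1225 ± 2.64 CPM, and Hsp90b1 and Pdia3 fell by 0.81 and 0.72 on the log2 scale. The RNA quality list of mitochondrial and nuclear RNAs moved together with these groups. Of its 16 genes, 9 rose (median log2 0.67, camera adjusted p = 0.00149, or adjusted p = 0.593 with an estimated correlation). Neat1 was at 371 ± 15.8 against 132 ± 6.72 CPM and mt-Co1 at 4879 ± 329 against 2869 ± 510 CPM.

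Camera called 16 of 30 lists, 10 up and 6 down. It asks whether a list moved more than the other genes, whereas fry asks whether a list's genes moved, on balance, one way. Fry called 21, with 15 called by both. RNA quality was the list called by camera whose fry adjusted p, 0.0766, did not pass. The remaining lists did not pass camera, with adjusted p = 0.655 for MHC class I presentation, 0.887 for matrix glycoproteins, 0.221 for matrix crosslinking and proteolysis, 0.265 for TGF-beta and YAP targets, 0.322 for angiogenic and growth factors, 0.47 for p53 targets, 0.106 for glycolysis, 0.417 for hypoxia, 0.185 for oxidative phosphorylation, 0.141 for fatty acid synthesis, 0.634 for NRF2 targets, 0.454 for ribosomal proteins, 0.887 for endothelial and 0.363 for adipocyte, pericyte and muscle markers. Single genes of these lists changed strongly all the same. The protease inhibitor Timp1 rose from 149 ± 6.08 to 784 ± 21.1 CPM, the angiogenic factor Vegfa from 87.5 ± 5.54 to 223 ± 4.45 CPM and ferritin heavy chain Fth1 from 1431 ± 25.4 to 3628 ± 171 CPM. The growth factor Igf1 fell from 156 ± 0.698 to 23.6 ± 1.06 CPM, Tgfb3 from 175 ± 7.61 to 39.7 ± 0.487 CPM and the fatty acid binding protein Fabp5 from 208 ± 9.43 to 34.1 ± 2.42 CPM. The TGF-beta list had a mean of 0.06 with a median of -0.02 and a downward test, and the endothelial list a median of 0.12 with a mean of -0.78 and a downward test. The number of genes higher fell to 1891 without control replicate 1, where the lone control library is assumed to vary like the other groups, and to 1944 with DESeq2. The TLR4 ligand call ended on the authors' filtered genes, which lack Saa3 (camera adjusted p = 0.165, with a range of 7.5e-10 to 0.165 over the alternatives), and without a filter (camera adjusted p = 0.0865). Oxidative phosphorylation passed without a filter (camera adjusted p = 0.00208, range 0.00208 to 0.448) and without 4T1 replicate 1 (0.022), and fatty acid synthesis (0.0371, range 0.0371 to 0.199) and ribosomal proteins (0.035, range 0.035 to 0.841) without 4T1 replicate 2.

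**Figure D1:**
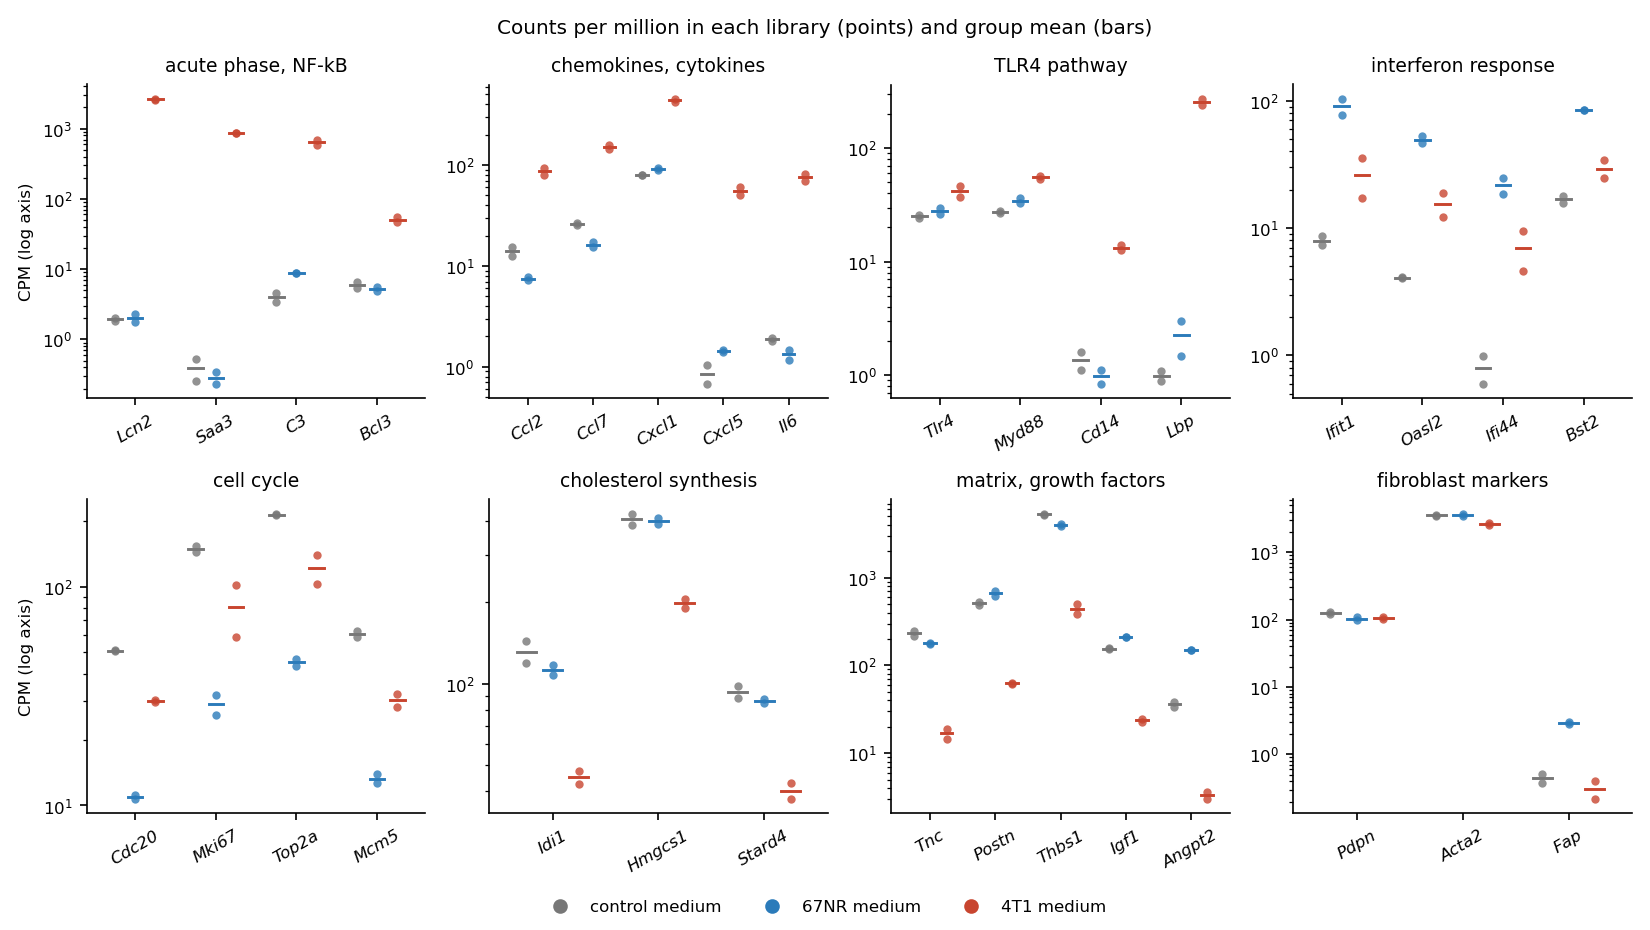
Expression in each library (points, CPM on a log axis) and group means (bars) for named genes in control, 67NR and 4T1 medium, 2 libraries per group. Lcn2 lies at 2612 ± 70.3 CPM in 4T1 medium against 1.94 ± 0.118 CPM in control medium, while Ifit1 is highest in 67NR medium at 90.7 ± 18.3 CPM.

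The comparison of 67NR medium with control medium asks what FRCs do in medium from the non-metastatic line. Interferon-inducible genes rose and cell cycle genes fell. Ifit1 (chromosome 19, 34640871 to 34650009), an RNA-binding antiviral protein, rose from 7.97 ± 0.92 to 90.7 ± 18.3 CPM (log2 3.52, SE 0.26, n = 2 per group, edgeR quasi-likelihood adjusted p = 7.59e-07). Oasl2 rose from 4.06 ± 0.0622 to 49.3 ± 4.4 CPM (log2 3.60, SE 0.18), and the membrane tether Bst2 (chromosome 8, 71534255 to 71537456) from 16.8 ± 1.41 to 84.7 ± 0.377 CPM (log2 2.33, SE 0.12). Cdc20 (chromosome 4, 118432901 to 118437352) fell from 51 ± 0.554 to 10.9 ± 0.347 CPM (log2 -2.22, SE 0.09, edgeR quasi-likelihood adjusted p = 1.97e-08). In all, 1951 genes were higher and 2199 lower, 27.6% of 15055, with 367 and 358 of them at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg). Fitted without the 4T1 libraries, 2570 were higher and 2755 lower. The same kind of fit for 4T1 and control medium alone gave 2607 and 2569.

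Of 25 interferon response genes, 24 rose and none fell, with a median log2 fold change of 2.66 (camera adjusted p = 3.18e-53, or adjusted p = 0.164 with an estimated correlation). Ifi44, Iigp1 and the protease Usp18 rose by 4.71, 3.94 and 3.58 on the log2 scale, and Rtp4, an interferon-induced gene outside the list, by 3.50. The Oas genes include close paralogs whose reads can be shared. MHC class I presentation followed, with 13 of 15 genes higher and none lower (median log2 0.80, camera adjusted p = 7.41e-14, or adjusted p = 0.155 with an estimated correlation). The non-classical class I gene H2-T23 rose from 21.5 ± 0.299 to 66.3 ± 1.26 CPM, the peptide transporter Tap1 from 17.9 ± 0.0896 to 45.5 ± 3.25 CPM and tapasin (Tapbp) from 96.2 ± 5.29 to 167 ± 0.83 CPM. H2 genes share sequence, so their separate levels are uncertain. All 25 mitosis genes fell (median log2 -2.24, camera adjusted p = 2.24e-122, or adjusted p = 0.155 with an estimated correlation). Besides Cdc20, the spindle checkpoint kinase Bub1 fell from 35.8 ± 1.15 to 5.48 ± 0.112 CPM, cyclin Ccnb1 from 27 ± 2.66 to 4.28 ± 0.69 CPM and the ubiquitin-conjugating enzyme Ube2c from 42.5 ± 0.0315 to 7.9 ± 0.0946 CPM. Of 27 DNA replication and S phase genes, 25 fell, 26 adjusted over the list alone (median log2 -1.13, camera adjusted p = 1.26e-41, or adjusted p = 0.155 with an estimated correlation). Ribonucleotide reductase Rrm2, Mcm5 and Mcm2 fell by 2.44, 2.19 and 1.25 on the log2 scale. Pbk, Clspn, Dlgap5 and Pclaf, further genes of the proliferating cell, fell by 2.58 to 2.61 on the log2 scale.

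The matrix lists were mixed in sign. Of 20 collagens, 9 rose and 7 fell (median log2 0.14, camera adjusted p = 0.000449, or adjusted p = 0.525 with an estimated correlation). Col6a2, Col6a1 and Col5a3 were higher by 1.13, 1.01 and 1.15 on the log2 scale. Of 24 matrix glycoproteins and proteoglycans, 11 rose, 12 adjusted over the list alone, and 4 fell (median log2 0.22, camera adjusted p = 6.48e-05, or adjusted p = 0.379 with an estimated correlation). Decorin (Dcn) rose from 48.6 ± 0.44 to 131 ± 1.7 CPM and thrombospondin Thbs2 from 548 ± 29.5 to 1277 ± 33.3 CPM. Of 14 complement and acute-phase genes, 6 rose and none fell (median log2 0.49, or 0.82 without Saa1 and Saa2, which had 0 counts in both groups and no bound, camera adjusted p = 2.66e-05, or adjusted p = 0.286 with an estimated correlation). They included C1s1, from 22.2 ± 2.15 to 62.5 ± 1.59 CPM, C4b (log2 1.62) and C1ra (log2 0.96). Of 19 glycolysis genes, 10 fell and 1 rose (median log2 -0.31, camera adjusted p = 3.5e-05, or adjusted p = 0.379 with an estimated correlation). Ldha, Pgam1 and Pgk1 were lower, at log2 values of -0.83, -0.73 and -0.70. Of 24 ATF4 target genes, 11 fell and none rose, against 11 and 1 adjusted over the list alone (median log2 -0.18, camera adjusted p = 0.00359, or adjusted p = 0.507 with an estimated correlation), such as the serine pathway enzymes Shmt2 (log2 -0.72) and Psph (log2 -0.69). Of 19 genes of the unfolded protein response, 7 rose, 11 adjusted over the list alone (median log2 0.16, camera adjusted p = 0.00466, or adjusted p = 0.379 with an estimated correlation), such as Sdf2l1 (log2 0.65) and Creld2 (log2 0.45). The RNA quality list moved with these groups, 10 of its 16 genes being higher, 12 adjusted over the list alone (median log2 0.50, camera adjusted p = 0.0017, or adjusted p = 0.635 with an estimated correlation). In that list mt-Co1 was at 4273 ± 605 against 2869 ± 510 CPM.

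Ccl2 and Ccl7 fell in 67NR medium, to 7.48 ± 0.361 and 16.3 ± 1.2 CPM (log2 -0.89 and -0.67, SE 0.14 and 0.09, edgeR quasi-likelihood adjusted p = 0.000386 and 0.000139). Values that did not pass were 28 ± 2.52 CPM for Tlr4 (log2 0.16, edgeR quasi-likelihood adjusted p = 0.337), 1.33 ± 0.222 CPM for Il6 (adjusted p = 0.191), 3593 ± 166 CPM for Acta2 (adjusted p = 0.848) and 91.1 ± 3.41 CPM for Cxcl1. The adjusted p of Cxcl1 was 0.0595, with a range of 0.0145 to 0.363 over the alternatives, and it passed in the fit of the 2 groups alone and without either 4T1 library. Fap rose from 0.445 ± 0.104 to 2.94 ± 0.0991 CPM (log2 2.67, SE 0.35), and the vessel-destabilising factor Angpt2 (chromosome 8, 18690263 to 18741562) from 36 ± 2.98 to 150 ± 1.37 CPM (log2 2.05, SE 0.08). Pdpn was 103 ± 8.76 CPM and passed (log2 -0.27, edgeR quasi-likelihood adjusted p = 0.0226). Its call ended without 67NR replicate 1 (adjusted p = 0.271, with a range of 0.0041 to 0.271 over the alternatives) or without control replicate 2 (adjusted p = 0.2).

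Camera called 11 of 30 lists, 7 up and 4 down, fry called 15 and both called 10. RNA quality was again called by camera and not by fry (adjusted p = 0.178). Camera adjusted p was 0.0941 for FRC markers, 0.672 for myeloid chemokines, 0.338 for the TLR4 receptor and adaptors, 0.753 for NF-kB targets, 0.107 for contractile genes, 0.107 for matrix crosslinking, 0.805 for TGF-beta and YAP targets, 0.107 for angiogenic factors, 0.237 for TLR4 ligands, 0.672 for p53 targets, 0.455 for hypoxia, 0.0777 for oxidative phosphorylation, 0.913 for cholesterol biosynthesis, 0.634 for fatty acid synthesis, 0.634 for NRF2 targets, 0.0777 for ribosomal proteins, 0.0716 for immune checkpoints, 0.491 for endothelial and 0.755 for adipocyte, pericyte and muscle markers. The NF-kB median was 0.06, or 0.02 without Nos2, which had too few counts in both groups for a bound. Median, mean and test differed in sign for chemokines (0.03, 0.05, down), TLR4 ligands (-0.13, 0.13, up), cholesterol biosynthesis (median -0.01, up), TGF-beta targets (-0.06, 0.07, down) and the adipocyte list (0.17, -0.16, down). The genes higher and lower numbered 1109 and 1350 without control replicate 1, 1089 and 1317 without control replicate 2, 1043 and 1184 without 67NR replicate 1, and 1112 and 1252 without 67NR replicate 2, the lone library being assumed to vary like the other groups. The RNA quality call ended without control replicate 1 (camera adjusted p = 0.0729, with a range of 7.01e-10 to 0.0729 over the alternatives). Oxidative phosphorylation passed without a filter (camera adjusted p = 0.00116, range 0.00116 to 0.163), and ribosomal proteins passed without a filter (0.00382, range 0.00382 to 0.258), without control replicate 1 (0.0217) and without 4T1 replicate 1 (0.0415) or 2 (0.0415).

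The direct comparison of 4T1 with 67NR medium asks what separates the responses to the metastatic and the non-metastatic line. Each kind is represented by a single line, so metastatic capacity cannot be told apart from other differences between the lines or their media. Inflammatory and acute-phase genes were higher in 4T1 medium, and interferon, collagen and contractile genes were lower. Ccl2 and Ccl7 were higher by 3.53 and 3.22 on the log2 scale (SE 0.12 and 0.08, edgeR quasi-likelihood adjusted p = 1.11e-10 and 1.35e-11), Il6 by 5.82 and Cxcl1 by 2.27. Angpt2 stood at 3.29 ± 0.415 CPM against 150 ± 1.37 CPM in 67NR medium (log2 -5.52, SE 0.11, edgeR quasi-likelihood adjusted p = 1.18e-12), and the matrix protein periostin (Postn, chromosome 3, 54361109 to 54391037) at 62.8 ± 1.23 against 663 ± 68 CPM (log2 -3.40, SE 0.09). Altogether 3542 genes were higher and 2989 lower in 4T1 medium, 43.4% of 15055, with 829 and 749 of them at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg).

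Of 14 complement and acute-phase genes, 12 were higher in 4T1 medium and 1 lower (median log2 4.52, or 3.16 with genes at 0 at their bound, camera adjusted p = 8.73e-65, or adjusted p = 0.0269 with an estimated correlation). Saa3, Lcn2 and the haemoglobin scavenger haptoglobin (Hp) were higher by 11.54, 10.32 and 8.37 on the log2 scale. Serpina3i had 1 count in 67NR and 678 in 4T1 medium, a ratio of 862 (95% counting interval 154 to 34085). Of 21 NF-kB targets, 17 were higher and 1 lower (median log2 1.79, camera adjusted p = 2.97e-49, or adjusted p = 0.0269 with an estimated correlation). Of 11 myeloid chemokines, 6 were higher and 2 lower (median log2 0.96, camera adjusted p = 1.36e-15, or adjusted p = 0.0903 with an estimated correlation). Of 18 genes of the TLR4 receptor and adaptors, 7 were higher and 1 lower (median log2 0.17, camera adjusted p = 0.00343, or adjusted p = 0.244 with an estimated correlation). Tlr4 was at 41.7 ± 7.01 against 28 ± 2.52 CPM (log2 0.58, SE 0.11, edgeR quasi-likelihood adjusted p = 0.000871), and Lbp was higher by 6.84 and Cd14 by 3.77 on the log2 scale. Of 12 TLR4 ligands, 6 were higher and 3 lower (median log2 0.27, camera adjusted p = 0.000279, or adjusted p = 0.12 with an estimated correlation). Of 12 FRC markers, 7 were higher and 1 lower, 2 adjusted over the list alone (median log2 0.56, camera adjusted p = 0.00109, or adjusted p = 0.244 with an estimated correlation). Vcam1 and Il33 were higher by 1.59 and 1.67 on the log2 scale, the receptor Pdgfrb was at 218 ± 21.2 against 505 ± 21.8 CPM, and Pdpn was equal within error at 105 ± 6 and 103 ± 8.76 CPM (edgeR quasi-likelihood adjusted p = 0.794).

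Of 25 interferon response genes, 21 were lower in 4T1 medium and none higher (median log2 -1.43, camera adjusted p = 3.09e-10, or adjusted p = 0.292 with an estimated correlation), such as the viral RNA sensors Ifih1 (log2 -1.43) and Ddx58 (log2 -1.01). Of 15 MHC class I genes, 11 were lower (median log2 -0.59, camera adjusted p = 1.35e-05, or adjusted p = 0.193 with an estimated correlation), with B2m, the invariant light chain, at 297 ± 12 against 648 ± 19.8 CPM. Of 20 contractile genes, 17 were lower (median log2 -0.64, camera adjusted p = 1.65e-06, or adjusted p = 0.0903 with an estimated correlation), including Mylk (log2 -1.17), Acta2 (log2 -0.44) and Fap (log2 -3.25). Of 20 collagens, 15 were lower and 1 higher (median log2 -0.72, camera adjusted p = 3.09e-10, or adjusted p = 0.244 with an estimated correlation), Col1a1 being at 6911 ± 274 against 15219 ± 557 CPM. Of 24 matrix glycoproteins, 13 were lower and 8 higher (median log2 -0.24, camera adjusted p = 0.023, or adjusted p = 0.435 with an estimated correlation). Tnc (log2 -3.40) and elastin (Eln, log2 -4.66) were lower and Has2 (log2 4.06) was higher. Itga8, an integrin chain, had 1 count in 4T1 and 544 in 67NR medium, a ratio of 428 (95% counting interval 76.5 to 16937) in favour of 67NR medium.

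All 25 mitosis genes were higher in 4T1 than in 67NR medium (median log2 1.43, camera adjusted p = 2.16e-18, or adjusted p = 0.244 with an estimated correlation), with Cdc20 at 30 ± 0.337 against 10.9 ± 0.347 CPM. Of 27 S phase genes, 17 were higher and none lower, 18 and 1 adjusted over the list alone (median log2 0.57, camera adjusted p = 0.00183, or adjusted p = 0.495 with an estimated correlation). Of 19 glycolysis genes, 12 were higher, 13 adjusted over the list alone, and 2 lower (median log2 0.36, camera adjusted p = 9.32e-06, or adjusted p = 0.244 with an estimated correlation), hexokinase Hk2 being at 83.1 ± 0.437 against 18.9 ± 0.719 CPM. All 23 cholesterol genes were lower (median log2 -0.83, camera adjusted p = 6.4e-15, or adjusted p = 0.193 with an estimated correlation), as were 18 of 19 genes of the unfolded protein response (median log2 -0.62, camera adjusted p = 3.09e-10, or adjusted p = 0.12 with an estimated correlation). Of 24 ATF4 targets, 22 were higher and none lower (median log2 0.76, camera adjusted p = 4.35e-14, or adjusted p = 0.12 with an estimated correlation). The RNA quality list did not differ past the threshold (median log2 0.16, camera adjusted p = 0.51).

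Camera called 17 of 30 lists, 10 up and 7 down, fry 22 and both 17. The lists that did not pass camera were matrix crosslinking (adjusted p = 0.923), TGF-beta and YAP targets (0.492), angiogenic factors (0.72), p53 targets (0.739), hypoxia (0.181), oxidative phosphorylation (0.923), fatty acid synthesis (0.0651), NRF2 targets (0.923), ribosomal proteins (0.683), immune checkpoints (0.105), endothelial (0.584) and adipocyte, pericyte and muscle markers (0.535). Median, mean and test differed in sign for crosslinking (-0.08, 0.27, up), TGF-beta targets (0.24, -0.01, down), p53 targets (0.10, 0.02, down) and oxidative phosphorylation (0.01, 0.01, down). The matrix glycoprotein call ended without 4T1 replicate 1 (camera adjusted p = 0.271, with a range of 0.00238 to 0.271 over the alternatives) and without a filter (camera adjusted p = 0.0804). The TLR4 ligand call ended on the authors' filtered genes, which lack Saa3 (camera adjusted p = 0.695, with a range of 4.15e-07 to 0.695), and without a filter (camera adjusted p = 0.0643). Fatty acid synthesis passed, downward, under 5 alternatives (camera adjusted p from 0.00935 to 0.0763 over all of them). These were no filter (0.00935), the replicate block (0.0272), equal depth (0.0491) and leaving out 67NR replicate 1 (0.0198) or 4T1 replicate 2 (0.0129). Immune checkpoints passed without 4T1 replicate 1 (camera adjusted p = 0.0318, range 0.0318 to 0.449).

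**Figure D2:**
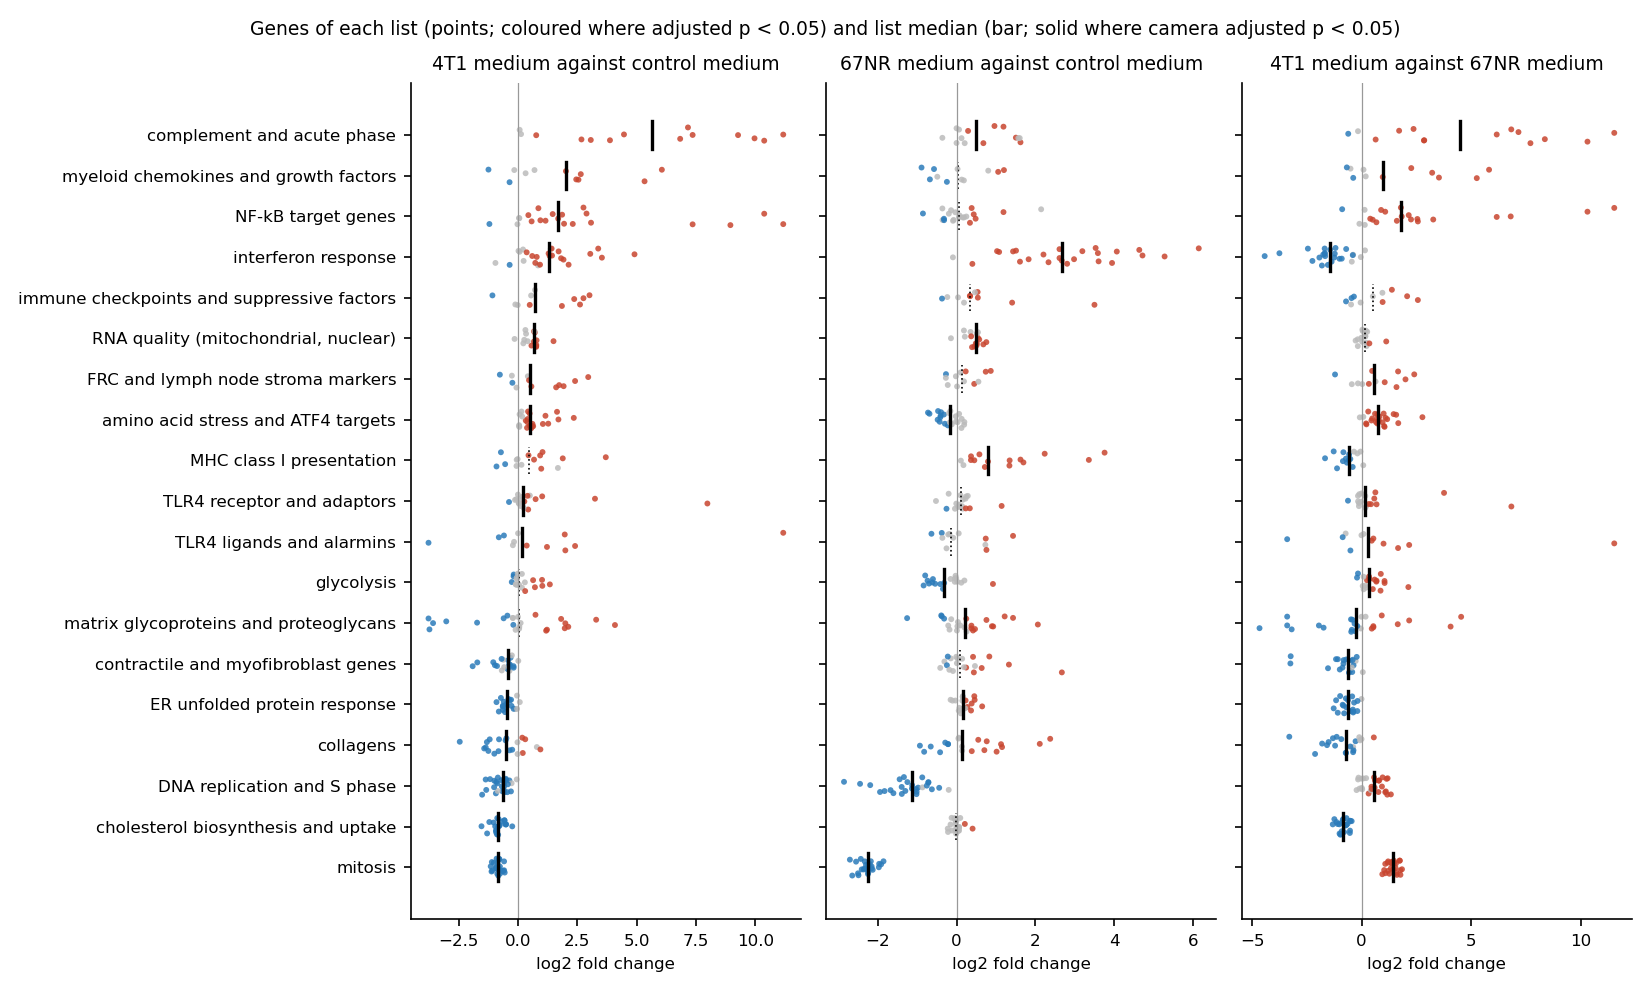
Log2 fold changes of the genes of each list (points, coloured where they passed edgeR) and list medians (bars, solid where camera called the list) in the 3 comparisons. Mitosis genes have a median of -2.24 in 67NR medium and -0.86 in 4T1 medium, and complement and acute-phase genes a median of 5.65 in 4T1 medium.

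The responses to both tumour media overlapped in part. Of the genes called in each, 767 were higher in both media (388 expected if independent) and 893 lower in both (423 expected), while 324 were higher in 4T1 and lower in 67NR medium (437 expected) and 374 the reverse (375 expected). The media still differed, by the direct edgeR quasi-likelihood test, for 363 of the genes higher in both and 438 of those lower in both. Both comparisons use the same 2 control libraries, so part of the excess may come from shared controls. With no effect simulated, the covariance of the 2 sets of log2 fold changes across genes was 0.0397 on average against 0.186 observed, a difference of 0.146. On log CPM the covariance was 0.128 with shared controls, and 0.0986 and 0.107 when each medium was set against its own control library. Genes are not independent replicates, and the correlation across genes was 0.363 against a simulated 0.519. Genes whose groups did not overlap made up 67.4% for 4T1 against control, 67.6% for 67NR against control and 70.1% for 4T1 against 67NR, where chance gives 33.3%. The covariance was 0.387 without control replicate 1, 0.304 without control replicate 2 and 0.926 without a filter on low counts.

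**Figure D3:**
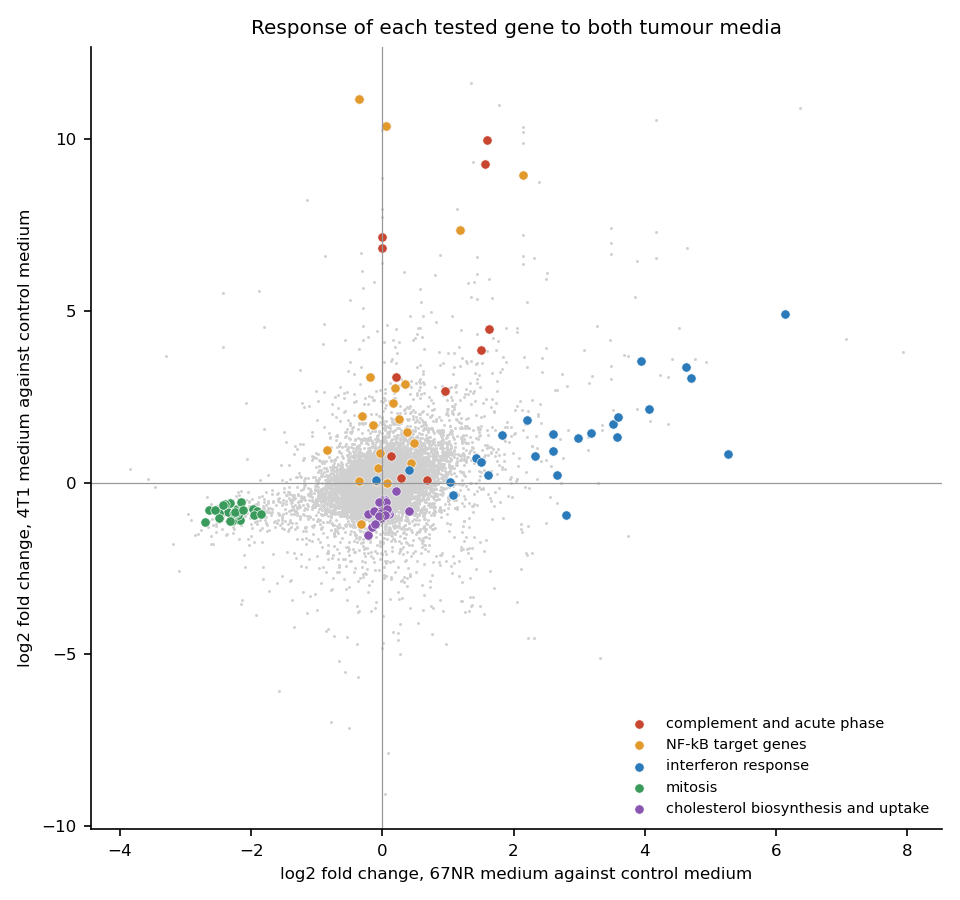
Log2 fold change of each tested gene in 67NR medium (horizontal axis) and in 4T1 medium (vertical axis), both against control medium, with 5 lists in colour and genes of more than 1 list in the colour drawn last. Interferon genes lie to the right (median 2.66 in 67NR medium and 1.29 in 4T1 medium), mitosis genes to the left, and acute-phase genes at the top.

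The 22 epithelial and mammary carcinoma markers, of which 4 passed the filter, summed to 9.98 ± 0.867 CPM in control, 7.93 ± 0.141 in 67NR and 4 ± 0.267 in 4T1 medium (SD, n = 2). The 22 macrophage and other leukocyte markers, of which 4 passed the filter, summed to 10 ± 0.997, 17.2 ± 0.543 and 12.9 ± 0.978 CPM. Both lists had too few tested genes for camera. The endothelial list, 8 of 17 markers tested, summed to 214 ± 3.92, 214 ± 7.01 and 250 ± 16.6 CPM, and the adipocyte, pericyte and muscle list, 5 of 17 tested, to 246 ± 4.94, 287 ± 8.2 and 274 ± 22.5 CPM.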

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

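The tests at equal depth for acute-phase and cell cycle genes were chosen before their results were seen, on thinned libraries that were added after the data had been examined, and the other 7 tests were chosen only after the result was seen.

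Median log2 fold changes of 17 lists differed between the tumour media when 4T1 was tested directly against 67NR medium. They were 0.56 for FRC markers, 0.96 for myeloid chemokines, 0.17 for the TLR4 receptor and adaptors, 1.79 for NF-kB targets, -1.43 for interferon response, -0.59 for MHC class I, -0.64 for contractile genes, -0.72 for collagens, -0.24 for matrix glycoproteins, 4.52 for complement and acute phase, 0.27 for TLR4 ligands, 0.57 for S phase, 1.43 for mitosis, 0.36 for glycolysis, -0.83 for cholesterol, 0.76 for ATF4 targets and -0.62 for the unfolded protein response. With an estimated correlation 2 of the 17 held (complement and acute phase, and NF-kB targets, both at adjusted p = 0.0269) and the other 15 were lost, at adjusted p = 0.0903 to 0.495. The largest camera adjusted p was 0.023, for matrix glycoproteins, a call that ended without 4T1 replicate 1 (camera adjusted p = 0.271, with a range of 0.00238 to 0.271 over the alternatives).

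Another 36 named genes were called in opposite directions by the media, each against the same control, a choice that by itself makes the media differ, so the direct test adds their size (edgeR quasi-likelihood adjusted p at most 1.14e-06, for Lyz2). Genes that rose in 4T1 and fell in 67NR medium differed by log2 values of 3.53 for Ccl2, 3.22 for Ccl7, 1.79 for the pentraxin Ptx3, 2.80 for Timp1, 2.78 for Cth, 2.14 for Hk2, 1.05 for Pfkl, 1.50 for Ero1l, 1.56 for the death receptor Fas, 1.05 for Shmt2, 1.01 for Psat1, 1.09 for Psph and 0.86 for Txnrd1. Genes that fell in 4T1 and rose in 67NR medium included matrix, adhesion and growth factor genes, at -8.44 for Itga8 (1 count in 4T1 medium, so the fitted value is no bound), -5.52 for Angpt2, -5.19 for Itgbl1, -4.66 for Eln, -3.40 for Postn, -3.14 for Igf1, -2.58 for Tgfb3, -2.13 for Col8a1, -1.51 for Col5a3 and -1.21 for Pdgfrb. The others were -4.94 for Tmem252, -4.77 for Plxdc2, -2.13 for lysozyme Lyz2, -1.43 for Ifih1, -1.28 for Calr, -1.12 for B2m, -1.27 for Ndrg1, -1.24 for Tm7sf2, -1.17 for Mylk, -1.17 for Sdf2l1, -1.09 for Creld2, -0.98 for Pdia4 and -0.93 for the cell cycle inhibitor Cdkn1b. In 67NR medium the call of Tm7sf2 ended without 67NR replicate 1 (adjusted p = 0.095, with a range of 0.00248 to 0.095 over the alternatives), without control replicate 1 (adjusted p = 0.0905) and with DESeq2 (adjusted p = 0.0652).

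Acute-phase and NF-kB genes were high in 4T1 medium, and at equal depth 25 of the 26 that rose still rose. Tumour cells or their RNA carried over with the medium would raise epithelial markers if 4T1 cells express them, which was not measured here. Yet the sum of these markers was 4.00 CPM against 9.98 CPM in control medium, a difference of -5.98 CPM. Leukocytes would bring their abundant transcripts, such as Ptprc, Tyrobp, Laptm5, Fcer1g, Itgam, Adgre1, Coro1a, Cd3e and Cd79a. These 9 genes, picked from the leukocyte list after the result, summed to 0.516 CPM in 4T1 medium and 0.201 CPM in control medium. Saa3 stood at 869 CPM in 4T1 medium. The full list of 22 was 12.9 ± 0.978 against 10 ± 0.997 CPM in control medium, and the leukocyte gene Cd53, outside the list, was 2.35 ± 0.367 against 0.175 ± 0.173 CPM. Also outside the list, the monocyte marker Ly6c2, which has close paralogs, was 39.1 ± 2.78 against 0.393 ± 0.0309 CPM. Plac8 was 4.13 ± 0.0116 against 0.0743 ± 0.105 CPM, while Lyz2, in the list, fell (log2 -1.33). All these levels were far below Saa3, and a small leukocyte share was not excluded. A response of the FRCs to something in 4T1 medium, or to the lack of something in control medium, stays open. Such a response may act through TLR4, IL-1, IL-6 or other receptors, and these were not tested apart.

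Cell cycle genes were low in 67NR medium. At equal depth 50 of the 50 genes that fell still fell. RNA quality alone would lower them as much in 4T1 medium, where the median of that list was 0.67 against 0.50 in 67NR medium. Yet 25 of 25 mitosis genes were lower in 67NR than in 4T1 medium. The same 25 genes also fell in 4T1 medium against control (median log2 -0.86), so a partial effect of RNA quality stays open. A p53 arrest would raise its targets. In the list of p53 targets and cell cycle arrest genes, 3 rose and 8 fell among 19 (4 and 8 adjusted over the list alone). Mdm2 was lower (log2 -0.20) and Cdkn1a was at 0.01. The largest rise in the list was that of the cell cycle inhibitor Cdkn1b (log2 0.65), which stands there as an arrest gene. A lack of growth factors or nutrients in the medium, or denser cultures, may contribute and was not tested.

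Interferon response genes were high in 67NR medium, and at equal depth 22 of the 24 that rose still rose. The epithelial sum was 7.93 against 9.98 CPM, a difference of -2.05 CPM. Of the 22 epithelial markers 4 passed the filter, and their level in 67NR cells was not measured. The sum therefore cannot tell whether 67NR RNA was carried over. The leukocyte list was higher, at 17.2 ± 0.543 against 10 ± 0.997 CPM in control medium, with Lyz2 at log2 0.80, and leukocyte RNA was not tested as a source. Whether the FRCs made interferon themselves or received it with the medium cannot be told apart. The 21 interferon genes had 14 counts in all in 67NR medium, 8 in control and 13 in 4T1 medium, and Ifnb1 had 4 counts in 67NR medium and 0 in the others, too few to decide.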

How the results depend on the processing

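The tests on libraries thinned to equal depth were added after the unthinned results had been seen, though for acute-phase and cell cycle genes before their thinned results, and all other alternatives here were planned. No gene called in a comparison was called in the opposite direction under any alternative. Of the calls, 97.2 to 97.8% held with DESeq2 size factors, 94.5 to 97.5% with library totals, 95.4 to 96.4% without a filter, 97.7 to 99.2% with limma-voom, 68.6 to 74.1% with the DESeq2 test, 88.2 to 91.1% at equal depth, 52.9 to 99.9% with a library left out, and 87.5, 99.7 and 92.9% in fits of the 2 groups compared. With DESeq2 the genes higher in 4T1 than control medium numbered 1944. The fits of the 2 groups compared called 5176 genes for 4T1 against control and 5325 for 67NR against control. The main fit called 5888 and 4150, so which tumour medium changed more genes depended on the fit. A 2-fold minimum, which by construction leaves fewer genes, left 815 higher and 620 lower for 4T1 against control, 367 and 358 for 67NR against control, and 829 and 749 for 4T1 against 67NR. With a library left out, whose lone partner is assumed to vary like the other groups, the genes higher in 4T1 than control medium ranged from 1891 (without control replicate 1) to 2931, and for 67NR against control from 1043 to 2497 higher and 1184 to 2840 lower. The low values there came where a control or 67NR library, from the groups compared, was left out. The high values came without a 4T1 library, which leaves as many samples. The fit pools the spread over groups, and 4T1 libraries varied most, at 7.61 times counting noise against 3.97 in control and 3.99 in 67NR medium. The replicate number as a block gave 3091 higher and 2966 lower, 2063 and 2319, and 3618 and 3050, 16, 11 and 18 lists and a covariance of 0.187. Replicate deviations correlated between groups at -0.0406, 0.00508 and 0.0685, so little of the deviation across genes was shared. In each group, however, replicate 2 had the higher mitochondrial and the lower ribosomal protein share. Whether the numbers pair the libraries was therefore not settled, and the labels do not say. The covariance of the responses was 0.926 without a filter, 0.135 on the authors' filtered genes, 0.173 with 10 counts in every library of a group, 0.164 at equal depth and 0.187 to 0.387 with a library left out (0.387 without control replicate 1, 0.304 without control replicate 2), and the cause was not tested. With an estimated correlation camera called 2, 0 and 2 lists. Under the alternatives other than that and fry, list calls were lost in 7 instances (TLR4 ligands, matrix glycoproteins and RNA quality) and gained in 15 (oxidative phosphorylation, ribosomal proteins, fatty acid synthesis and immune checkpoints). Single named genes kept their side of the threshold in 3449 instances, lost it in 29 (Krt19, Tm7sf2, Myd88, Neat1, Rpl37 and Pdpn in 67NR, Pdpn in 4T1 medium, Atp5b between media) and passed newly in 3 (Cxcl1 in 67NR medium). A single count stood for up to 0.0743 CPM, so changes below that level are out of reach.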

Other observations

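The genes in this part were chosen after their values were seen, and so were the tests reported for them, which come from the planned fit of all genes.

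Single genes are given here for 4T1 medium against control. Socs3, a feedback inhibitor of JAK and STAT signalling, went from 15.7 ± 1.93 to 217 ± 8.78 CPM (mean ± SD, n = 2, edgeR quasi-likelihood adjusted p = 1.02e-11) and was 18.6 ± 1.47 CPM in 67NR medium. The kinase Jak2 went from 55.8 ± 1.72 to 421 ± 49.4 CPM, the interleukin 4 receptor Il4ra from 26.6 ± 0.68 to 275 ± 30.7 CPM, its partner Il13ra1 from 10.2 ± 0.463 to 151 ± 7.48 CPM, the oncostatin M receptor Osmr from 213 ± 3.92 to 701 ± 78 CPM and the interleukin 1 receptor Il1r1 from 38.8 ± 4.33 to 154 ± 20.3 CPM. Ly6a, a surface marker of mesenchymal progenitors with close paralogs, went from 20.1 ± 1.56 to 1166 ± 28.9 CPM. The zinc importer Slc39a14 went from 82.5 ± 1.54 to 452 ± 43 CPM. Aldh1a1 and Dhrs3, enzymes of retinoid metabolism, fell from 390 ± 24.7 to 56.4 ± 4.31 CPM and from 48.5 ± 0.00678 to 11.8 ± 0.857 CPM.

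Further single genes concern 67NR medium against control. The RNA sensor Dhx58 went from 3.27 ± 0.519 to 23.1 ± 0.466 CPM, Ifi27l2a from 1.92 ± 0.512 to 20.2 ± 1.38 CPM, Parp14 from 4.57 ± 0.366 to 22.3 ± 0.834 CPM and Xaf1 from 31.5 ± 6.01 to 135 ± 3.08 CPM, each lower in 4T1 than in 67NR medium (log2 -1.32, -1.82, -1.21 and -1.36, edgeR quasi-likelihood adjusted p at most 1.9e-06). Zbp1, a nucleic acid sensor, was 0.593 ± 0.629 CPM in control, 7.46 ± 0.595 in 67NR and 12.1 ± 1.08 in 4T1 medium.

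The authors' filtered table holds the genes with at least 10 counts in at least 3 of the 6 libraries, a rule that all 14629 of its genes meet. With 2 libraries per group, a gene expressed in a single medium cannot meet it. Of the genes tested here, 441 are absent from that table, and 166, 55 and 182 of them were called in 4T1 against control, 67NR against control and 4T1 against 67NR medium. Absent were 14 of the 20 largest rises and 86 of the 168 rises of at least 8-fold in 4T1 medium against control, among them Saa3 (869 ± 10.5 CPM in 4T1 medium), Serpina3n (220 ± 20.9 CPM) and Steap4 (61 ± 7.4 CPM). The filter took at most 0.261% of any library's total.

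Some genes were counted at levels far below those of close partners. In control medium Col1a2 had 13.4 ± 3.16 CPM beside 13817 ± 399 CPM of Col1a1, Col6a3 5.11 ± 2.18 CPM beside 1433 ± 54.5 CPM of Col6a1, Tagln 2.01 ± 0.202 CPM beside 3539 ± 95.7 CPM of Acta2, and Gapdh 6.97 ± 0.236 CPM beside 348 ± 5.39 CPM of Pgk1. The levels of these low genes are given as counted, and their changes between media carry that limit.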
